A study of Mus musculus with 54 samples.

How the data were processed

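The deposited data used here were 4 processed Hi-C tables, a loop list and a domain list for each of the parental and gemcitabine-resistant mouse pancreatic cancer cells. The sample labels name gemcitabine as the drug of the resistant Hi-C samples and the series text names doxorubicin, and the sample labels were followed. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, digested with DpnII, filled in with biotin, ligated, sheared and pulled down. The labels name 6 Hi-C samples, described as biological replicates, and the lists give 1 set of calls per condition. Whether the replicates were pooled before calling is not given in the sources used here. The 48 RNA-seq, ATAC-seq and ChIP-seq samples were not analysed here. BWA and the builds mm10 and hg19 are named in the submitters' processing notes for these samples. The caller of loops, the caller of domains and their settings are not given in the sources used here.

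Per the file headers, each loop has a p-value from the authors' caller. The deposited p-values were at most 0.0497, so loops above the authors' threshold were not seen here, and the model behind the p-value is not given in the sources used here. Per the file headers, each domain has a separation score, deposited with no statement of its scale or of the border it belongs to. In domains that had the same left border and different right borders in both lists, the scores had a Pearson r of 0.964 over 987 domain pairs. Pairs with the same right border only had an r of 0.629. Domains on 1 chromosome are not independent replicates, and the score was taken to belong to the left border. Scores and p-values were used to rank calls within a list. A list of fewer reads gives fewer and weaker calls, and the read depth of the samples is unknown, so counts of condition-specific calls can move with depth as well as with the cells.

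Coordinates are those of the lists, written from 1. They lie within the mouse chromosomes, and gene coordinates came from an annotation of the same mouse assembly, mm10. As a check of the build, 15.6% of parental anchor bins held a gene end at their own position and 12.1% or fewer when moved by 20, 100 or 500 kb. The annotation used gave no strand and no transcript starts, so both ends of each of 21631 protein-coding genes stood in for the gene start that had been planned. Motif searches for CTCF and forkhead factors, also planned, need a genome sequence and were not run.

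A loop was counted as found in both lists when each of its anchors lay within 10 kb of those of a loop of the other list, and a border when a border of the other list lay within 20 kb. Distinct anchor bins and distinct borders were counted once each. A loop was assigned to a gene when an anchor bin lay within 5 kb of a gene end. Overlap expected by chance came from 1000 circular shifts by at least 1 Mb per chromosome, and permutation p-values are one-sided with 0.001 as the smallest value. Differences of medians and of shares have intervals from 1000 resamples of the chromosomes. Shares and count ratios have exact Clopper-Pearson 95% intervals. Intervals cover counting error or chromosome spread, not the variation between cultures. No test between conditions was made, since each has 1 list.

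The 20 gene lists held 470 genes, of which 1 had no match in the annotation. For each list the resistant-only minus parental-only loops were summed over its genes and placed among 10000 random lists of as many genes matched on the number of loops. Percentiles below 2.5 or above 97.5 are called outside. The rule for named genes, set before the data were examined, took the Foxa genes, up to 6 members per list with the largest difference, 10 further genes per direction, and 5 loops and 5 borders per condition. It left out predicted genes with symbols of Gm and digits or ending in Rik, but not those starting with LOC. Of the list members it took, examples are named, and some of the genes it took are not reported here. The 3 loops named among those found in both lists were chosen after their values were seen.

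Alternatives were other tolerances, one-to-one matching, a stricter threshold that kept the 3414 parental and 3584 resistant loops of lowest p-value, the same for domains by score, lists of equal length, autosomes, limits on span and size, reciprocal overlap and other gene windows. Lists of equal length held the 5122 loops of lowest p-value from each list, so this setting also left out weak calls. Gene bodies in place of gene ends, and loops over 15 kb only, were added after the data were seen. The steps were tested on simulated data before use. Of 6829 simulated loops with 40% copied between lists, 40.3% were found in both. None of 40 simulated lists without shared loops gave a p of 0.05 or lower, and 2 of 40 unchanged gene lists fell outside the limits. The lists without shared loops were made by the same circular shifts that tested them, so they check the steps only. The unchanged gene lists had classes drawn for each gene independently. They do not show that the limits hold for neighbouring genes that share loops, such as the Hox genes. Of borders with 80.0% kept, 80.1% were found. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.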

Results

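The series compared mouse pancreatic cancer cells that were never selected with the drug, called parental here, with cells grown resistant to gemcitabine, a nucleoside analogue used against pancreatic cancer. The labels list 54 samples in 18 groups of 3. Hi-C, which ligates and sequences pairs of DNA ends that lie close together in the nucleus, was made for 3 parental samples treated with DMSO and 3 resistant samples treated with gemcitabine. Resistance and drug treatment thus went together in the Hi-C samples, and the lists cannot tell them apart. The sample labels name gemcitabine, while the series text names doxorubicin for the Hi-C part, and the sample labels were followed. The values analysed here were the deposited Hi-C calls, with 1 list of chromatin loops and 1 list of topologically associating domains per condition. Each loop joined 2 bins of 5 kb on the same chromosome and carried a p-value. Domains, drawn on bins of 10 kb, are stretches of a chromosome that contact themselves more than their surroundings. With 1 list per condition there was no replicate error, so no difference between the conditions could be tested and none is called a change. Read depth behind the lists is unknown. Intervals given below are exact binomial 95% intervals or intervals from resampled chromosomes, and they cover counting error or the spread between chromosomes only.

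The comparison asked which chromatin loops the parental and the resistant cells had in common. Among the strongest loops found in both lists with a gene at an anchor, 1 on chromosome 6 joined bins within 5 kb of ends of Ghrhr and Adcyap1r1. Both genes encode receptors of peptide hormones (bins at 55390001 to 55395000 and 55505001 to 55510000, mm10, caller's p 4.47e-13 in the parental list). Another on chromosome 4 started at Tnfrsf1b, a receptor of tumour necrosis factor, and a further one on chromosome 2 started at Elf5, an epithelial transcription factor, and Cat, the gene of catalase. The parental list held 6829 loops and the resistant list 7169. Of these, 2541 loops were found in both lists with each anchor within 10 kb, which was 37.2% of the parental list (36.1 to 38.4) and 35.4% of the resistant list (34.3 to 36.6). The other 4288 parental loops and 4628 resistant loops are called parental-only and resistant-only below.

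The overlap exceeded chance. In 1000 circular shifts of the resistant list along each chromosome, a mean of 0.591% and at most 0.864% of parental loops found a partner (one-sided permutation p = 0.001, the smallest the shifts can give). Anchors were found in both lists more often than whole loops, at 50.5% of the 12729 parental anchor bins and 48.2% of the 13388 resistant anchor bins, against shift means of 11.9% and 11.4%. Both anchors were in use in the other list for 8.56% of parental-only loops (7.74 to 9.44) and 8.28% of resistant-only loops (7.5 to 9.11). Neither anchor was in use there for 59.8% and 62.2%.

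Loops with the lowest p-values were found in both lists most often. In the strongest decile of the parental list 83.3% of loops had a match (80.3 to 86.0), and in the weakest decile 3.52% (2.27 to 5.19). The resistant list gave 82.2% and 4.05%. The median p was 2.38e-06 for parental loops with a match and 0.000977 for parental-only loops, and 2.83e-06 and 0.00112 in the resistant list. Median loop span was 110 kb in both lists, with quartiles of 55 and 210 kb in parental cells and 55 and 215 kb in resistant cells. Loops of at most 15 kb numbered 527 and 575, and only 9.68% and 8.00% of them had a match. Under a stricter p-value threshold the difference of medians in loop span was -10.0 kb (-15 to -5.0), resistant minus parental. Under a tolerance of 0 kb, with identical bins, loop sharing was 16.0% of the parental list. For loop sharing, resistant list, the stricter threshold gave 50.3%, and 52.8% of parental loops then had a match.

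**Figure D1:**
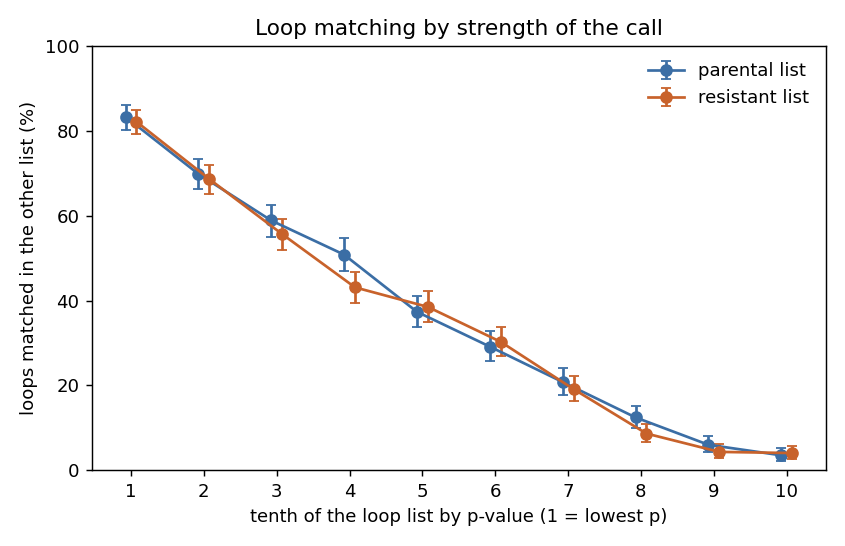
Percent of loops with a match in the other list (vertical axis) for each decile of the loops ordered by p-value (horizontal axis, 1 is the lowest p), with points for the parental and the resistant list and bars for exact binomial 95% intervals. Matching fell from 83.3% to 3.52% in the parental list and from 82.2% to 4.05% in the resistant list.

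The strongest condition-specific loops touched genes of several kinds. In resistant cells the leading resistant-only loop with a gene at an anchor ran over 465 kb on chromosome 10 from Hey2, a transcriptional repressor downstream of Notch (bins at 30830001 to 30835000 and 31295001 to 31300000, caller's p 3.3e-11). It was followed by a 45 kb loop on chromosome 9 between Ap1m2, an epithelial subunit of a vesicle coat adaptor, and Slc44a2, a choline transporter-like protein (caller's p 1.14e-10). The next were loops from Ctrb1, the digestive enzyme precursor chymotrypsinogen, on chromosome 8 (caller's p 1.54e-10), from Rhcg, an ammonium transporter, on chromosome 7 (caller's p 1.6e-10) and from Prkci, an atypical protein kinase C of cell polarity, on chromosome 3 (caller's p 2.33e-10). In parental cells the strongest parental-only loop with a gene at an anchor was a 175 kb loop on chromosome 9 to Piwil4, a piRNA-binding protein of the germ line (caller's p 1.19e-10). Loops at Qprt and Spn on chromosome 7 (caller's p 2.75e-10), at Tex44 on chromosome 1 (caller's p 3.99e-10), at Tmem163 on chromosome 1 (caller's p 1.01e-09) and between Nemf and Vcpkmt with Sos2 on chromosome 12 (caller's p 1.05e-09) followed. Qprt makes a precursor of NAD, Spn is the leukocyte surface protein sialophorin, Tmem163 is a zinc transporter and Sos2 activates Ras.

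Genes were then ranked by their resistant-only minus parental-only loops, counted where an anchor bin lay within 5 kb of an end of the gene. The largest difference was 4 loops in both directions. Radil, an adhesion protein acting downstream of Rap, Pappa2, a protease of insulin-like growth factor binding proteins, Atp8b1, a phospholipid flippase, Cebpa, a transcription factor of myeloid and fat cell differentiation, and Tnfsf13, a B cell cytokine, had 3 resistant-only loops each and no parental loop. The same counts were found for Cep20, a centrosomal protein, Ptger4, a prostaglandin receptor, Klf7, a Kruppel-like transcription factor, and Mtfmt, which formylates the mitochondrial initiator tRNA. In the other direction Kif26b, a kinesin family member (chromosome 1, 178529125 to 178932857), had 4 parental-only loops and no resistant loop. Zwilch of the kinetochore, Camk1d, a calmodulin-dependent kinase, Slc47a1, an exporter of organic cations and drugs that shared its loops with its neighbour Slc47a2, Mterf1b, a mitochondrial transcription factor, and Stam, of endosomal sorting, had 3 parental-only loops each and no resistant loop. Chek2, a checkpoint kinase of the DNA damage response, Plscr4, a phospholipid scramblase, Etf1, the release factor of translation, and Ssh2, a cofilin phosphatase, had the same counts. Some of these loops were weak calls: 1 Etf1 loop joined adjacent bins (span 5 kb, caller's p 0.0381). So were 1 Ssh2 loop (caller's p 0.0179) and 1 Kif26b loop (caller's p 0.01996). The genes named above for resistant-only loops had no call this weak.

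At a difference of 3 or more loops, such genes were within the numbers that a random assignment of the same loops gave. This difference of 3 or more loops was reached by 16 genes toward resistant and 19 toward parental cells. Dealing the 8916 condition-specific loops out at random 1000 times gave means of 19.6 genes (12.0 to 28.0) and 15.3 genes (7.97 to 24.0). At a difference of 2 or more, 234 genes leaned to resistant cells, within the random range of 231 to 299. The 261 genes that leaned to parental cells lay above the random range of 196 to 256.

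Foxa1, Foxa2 and Foxa3, which encode forkhead pioneer factors of foregut tissues, had 5 parental and 3 resistant loops in all. Foxa1 (chromosome 12, 57540628 to 57548029) had 1 loop in each list, the same one, reaching a bin at 57280001 to 57285000. Its caller's p was 6.55e-08 in the parental and 0.000372 in the resistant list. P-values rank calls within a list and read depth is unknown, so these 2 values do not show a weaker loop in resistant cells. Of all loops found in both lists, 47.4% had the lower p in the resistant list. Foxa2 (chromosome 2, 148042877 to 148046969) had 3 parental and 2 resistant loops, of which 2 were parental-only and 1 was resistant-only. The Foxa2 loop found in both lists had a caller's p of 7.76e-06 in the parental and 1.43e-06 in the resistant list. Foxa3, on chromosome 7, had 1 parental-only loop, of 15 kb (caller's p 0.000294), and no resistant loop.

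The 20 gene lists fixed before the data were examined asked whether loops at genes of drug handling, cell identity or signalling leaned to 1 condition. Hox genes, which set position along the body axis, leaned most to parental cells: 10 of the 39 had more parental-only loops, 3 had more resistant-only loops and 26 had no difference. Hoxa13 had 3 parental-only and no resistant-only loops, Hoxb8, Hoxb9 and Hoxc4 had 2 and none, and Hoxc10 had none and 2. The 2 Hoxc4 loops were weak calls (caller's p 0.0117 and 0.0123). The summed difference of -11 lay at percentile 0.305 among 10000 random lists matched on the number of loops. Acinar cell markers, genes of digestive enzymes, leaned to resistant cells in 5 of 17 members, among them Prss2, Ctrb1, Ctrl and Pnlip by 1 loop each. The Pnlip loop was a weak call (caller's p 0.0263). The sum of 6 over the list lay at percentile 99.5. The other 18 lists lay within the central 95% of their random lists.

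Both leanings rested on few loops and on how they were counted. Neighbouring Hox genes share anchors, and with each loop counted once there were 9 parental-only and 3 resistant-only loops, a resistant-only share of 25% (5.49 to 57.2) beside 51.9% of all condition-specific loops. For acinar markers the counts were 1 and 7, a share of 87.5% (47.4 to 99.7). When the condition-specific loops were dealt out at random with all their genes, 4.67% of draws gave a Hox sum as low and 4.81% an acinar sum as high. With gene ends required inside the anchor bin no list lay outside the limits.

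Among genes that take up, activate or break down gemcitabine, 5 of 26 leaned to resistant and 6 to parental cells (percentile 17.0). Samhd1, a phosphohydrolase of deoxynucleotides, and Nt5c, a nucleotidase, each had 2 parental-only loops, and Dck, the kinase that activates gemcitabine, had 1. Cmpk1, which adds the next phosphate, and Nt5e, an ectonucleotidase, each had 1 resistant-only loop. Drug efflux transporters had 1 loop in each class (percentile 49.2), at Abcc4 in parental and Abcc10 in resistant cells. Detoxification and redox genes leaned to resistant cells in 5 members and to parental cells in 3 (percentile 82.3). There were 2 resistant-only loops at Gsr, glutathione reductase, and 1 each at Gclc and Gclm, which make glutathione. Of these, 1 Gsr loop (caller's p 0.0182) and the Gclm loop (caller's p 0.01025) were weak calls. The 3 members that leaned to parental cells, among them G6pdx, had 1 parental-only loop each. DNA damage genes lay at percentile 59.7, with Wee1, a kinase that delays mitosis, at 2 resistant-only loops against the 3 parental-only loops of Chek2. A weak call was among the Wee1 loops (caller's p 0.0135). Apoptosis regulators lay at percentile 92.6, and Bcl2, which blocks apoptosis, had 3 resistant-only loops and no parental-only loop.

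Foregut and pancreatic transcription factors leaned to resistant cells in 8 of 29 members and to parental cells in 6 (percentile 74.6). Onecut1, a hepatic and pancreatic factor, had 2 resistant-only loops, and Gata5 and Gata6 leaned to resistant cells by 1. Epithelial and classical-subtype genes summed to 0 (percentile 49.1), with Reg4 at 2 parental-only loops and Cdh1, E-cadherin, at 1 resistant-only loop. The Cdh1 loop joined adjacent bins (span 5 kb, caller's p 0.01785), and only 8.00% of resistant loops of at most 15 kb had a match. Basal and squamous genes had 2 resistant-only loops (percentile 93.4), at Dsg3 (caller's p 0.0117) and Ly6d (caller's p 0.000126). Mesenchymal transition genes summed to 0 as well (percentile 48.4), although Cd44, a hyaluronan receptor, had 3 resistant-only loops and no parental-only loop. Pancreatic cancer drivers leaned to parental cells in 6 of 27 members and to resistant cells in 2 (percentile 9.08). Met, the hepatocyte growth factor receptor, had 2 parental-only loops, Cdkn2b, a cell cycle inhibitor, had 1, and Fgfr2 had 1 resistant-only loop. The Fgfr2 loop was a weak call (caller's p 0.0147).

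Cohesin, CTCF and chromatin regulators lay at percentile 85.8, with 2 resistant-only loops at Smc3 and 1 at Smc1a, both cohesin subunits. Wnt, Notch and Hedgehog genes lay at percentile 67.1, with 2 parental-only loops at Tcf7l2 and 2 resistant-only loops at Hey1, which leaned to parental cells by 1 loop under a stricter p-value threshold. Inflammatory genes lay at percentile 72.9, with 2 resistant-only loops at Icam1, a leukocyte adhesion molecule. Housekeeping genes lay at percentile 71.0. Of the markers of other cell types, endocrine cells lay at 48.5, endothelial cells at 64.9, immune cells at 32.5 and fibroblasts and stellate cells at 13.1, with 2 parental-only loops at Pdgfra.

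**Figure D2:**
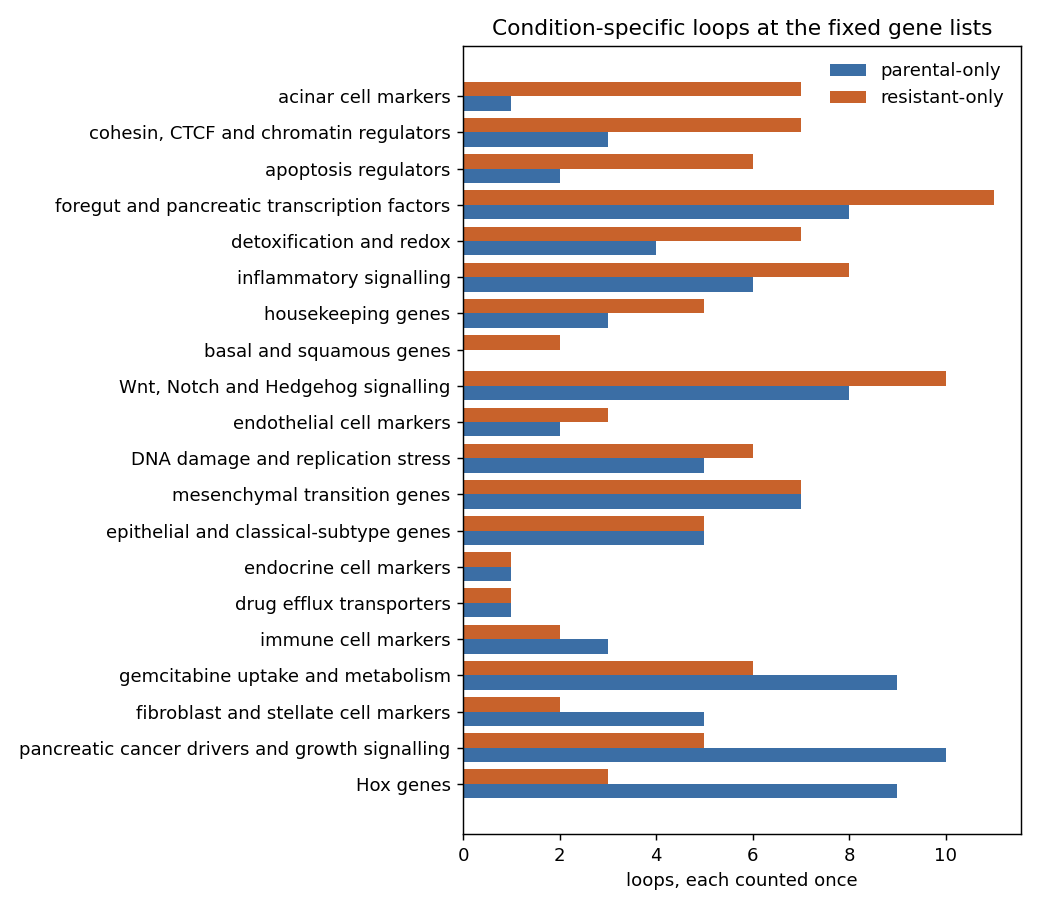
Number of parental-only and resistant-only loops (horizontal axis, loops counted once each) with a gene of the list at an anchor, for the 20 fixed gene lists (vertical axis). Hox genes had 9 parental-only and 3 resistant-only loops, and acinar cell markers 1 and 7.

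Loops touched genes in both conditions to a similar extent. Loops were at a gene end in 65.7% of loops found in both lists (63.8 to 67.6), in 45.3% of parental-only loops (43.8 to 46.8) and in 44.4% of resistant-only loops (43.0 to 45.9). Shifted loops were at a gene end in 29.5%, 28.7% and 28.8% (one-sided permutation p = 0.001 for each class, the smallest the shifts can give). The resistant-only share minus the parental-only share was -0.866 percentage points (-3.0 to 0.956). This difference was planned for promoter loops and was counted at either gene end, without telling starts from ends. Its interval excluded 0 among loops of 100 kb or longer, at -3.42 points (-6.59 to -0.849), with gene ends within 10 kb, at -1.94 points, and with gene bodies, a setting chosen after the data were seen, at -2.36 points. Of 21631 protein-coding genes, 2860 had loops in both lists, 2174 in the parental list only and 2294 in the resistant list only.

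Most single domain borders were found in both lists, and a smaller share of domains had both borders matched. The resistant-only border with a protein-coding gene within 50 kb that lay farthest from any parental border, at position 6030000 of chromosome 14 near LOC115488283, lay 1740 kb away from it. The next, on chromosome X at 64290000 near Slitrk4, a neuronal transmembrane protein, lay 1420 kb away. Others were at Esp34, an exocrine gland peptide, on chromosome 17, Ptprd, a receptor phosphatase, on chromosome 4 and Grm7, a glutamate receptor, on chromosome 6, with distances from 1110 to 1310 kb. Parental-only borders of this kind were at Rpl10l on chromosome 12 and Gpc6, a glypican, on chromosome 14, both 1090 kb away, at Aga, a lysosomal enzyme, on chromosome 8, at Cep290, a cilium protein, on chromosome 10 and at Zfhx4, a zinc finger homeobox factor, on chromosome 3.

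In the region around the Slitrk4 border, from 59180001 to 65710000 of chromosome X, the parental list held 2 domains of 2.93 and 3.60 Mb. The resistant list held 9 domains there, from 0.28 to 1.48 Mb, inside the same outer borders. The region was reached through a border picked for its distance, and it is an extreme case. Most divided parental domains had 2 parts.

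**Figure D3:**
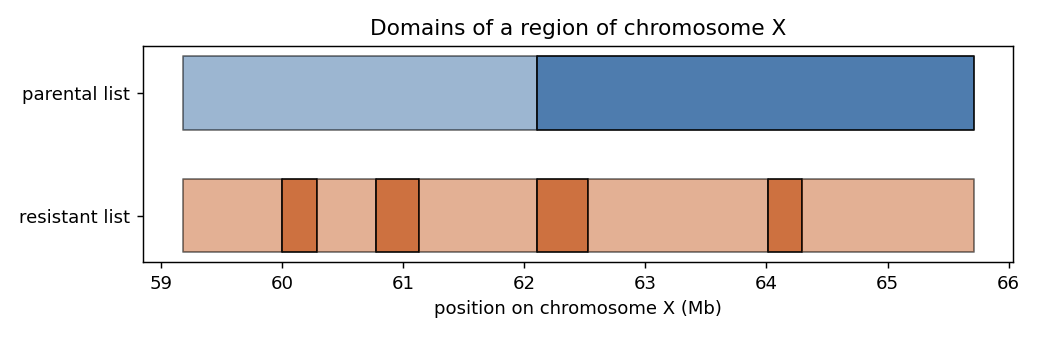
Domains of the parental and the resistant list (tracks) along chromosome X (horizontal axis in Mb, mm10), each box 1 domain, with alternating shades. The parental list has 2 domains where the resistant list has 9. The region was chosen for a border far from any parental border and is an extreme case.

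Counted over the genome, the parental list had 3997 domains and the resistant list 4196, with median sizes of 510 and 500 kb and a difference of -10.0 kb (-20 to 0). Under a stricter score threshold the difference in domain size was -40.0 kb (-50.0 to -10.0). Within 20 kb, 82.4% of parental borders (81.2 to 83.5) and 78.5% of resistant borders (77.2 to 79.7) were found in the other list, against 8.21% and 7.85% under shifts (one-sided permutation p = 0.001, the smallest they can give). Both borders matched for 62.6% of parental and 59.6% of resistant domains. Of the parental domains, 257 were divided by borders of the resistant list into 2 or more parts, and 143 resistant domains were divided in the parental list. Most had 2 parts, at 214 of the 257 and 135 of the 143, with at most 5 and 3 parts. The authors' separation score had a median of -0.416 at parental borders with a match and -0.260 at parental-only borders. The resistant list gave -0.439 and -0.250.

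Loops mostly stayed inside domains. Of parental loops 3.73% spanned a parental border (3.30 to 4.21), and of resistant loops 3.98% spanned a resistant border (3.53 to 4.45), against 17.4% and 18.0% with shifted borders (one-sided permutation p = 0.001 for fewer, the smallest the shifts can give). Loops found in both lists spanned a parental border in 1.22%, and parental-only loops in 5.22%. Parental-only borders were spanned by 1.64% of resistant-only loops (1.30 to 2.05) and 1.73% of parental-only loops, below the 3.16% and 3.21% of shifted borders. Resistant-only borders were spanned by 1.92% and 2.24% of them, below the 4.01% and 3.99% of shifted borders. Anchors lay within 20 kb of a border of their own list in 13.4% of parental and 14.7% of resistant anchor bins, against 6.30% and 6.59% for shifted borders (one-sided permutation p = 0.001, the smallest they can give).

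By chromosome, the resistant list had more loops on 12 and fewer on 8, with a ratio of 1.05 over the genome. Chromosome 7, which carries Cebpa and Foxa3, had 347 parental and 451 resistant loops, a ratio of 1.30 (1.13 to 1.5). Chromosome X had 175 and 237, a ratio of 1.35 (1.11 to 1.66). These were the 2 chromosomes of 20 whose interval excluded 1.05. With 20 intervals some can miss it by chance, and loops on 1 chromosome are not independent, so the intervals may be too narrow. With lists of equal length, 5122 loops each, the ratio over the genome is even by construction. The loops per chromosome, 7 first, then had a ratio of 1.11 (0.942 to 1.31). For the loops per chromosome, X next, the ratio was 1.28 (0.949 to 1.72). Both intervals included an even ratio, and 1.05 as well. On chromosome 7 a stricter p-value threshold gave 1.18 (0.970 to 1.43), an interval that included 1.05. That threshold gave a ratio of 1.67 (1.09 to 2.59) on X, above 1.05. Domains were more numerous in the resistant list on 19 chromosomes and fewer on chromosome 8, and no interval excluded the genome-wide ratio. On X only 25 loops were found in both lists, 14.3% of parental loops (9.46 to 20.4) and 10.5% of resistant loops (6.94 to 15.2), beside 37.8% and 36.3% on the autosomes. Loops on X had median p-values of 0.00405 and 0.00300 and a median span of 25 kb in both lists.

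**Figure D4:**
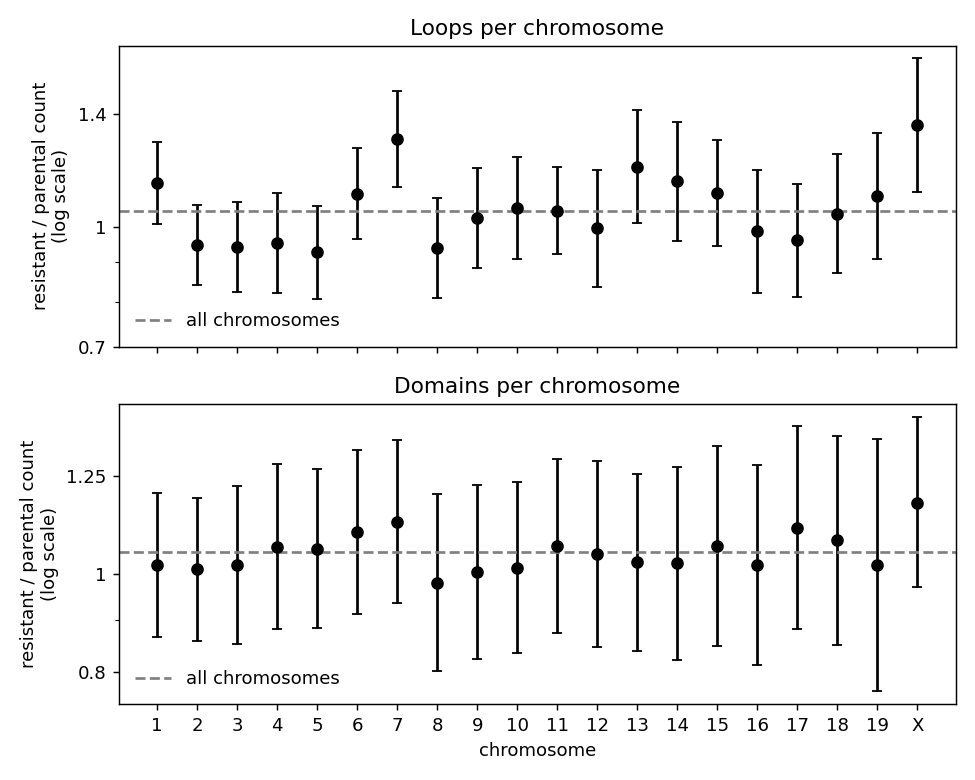
Ratio of resistant to parental counts (vertical axes, log scale) of loops (upper panel) and domains (lower panel) for each chromosome (horizontal axis), with exact binomial 95% intervals and a dashed line at the ratio over all chromosomes. The loop intervals of chromosomes 7 and X lie above the line of 1.05.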

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

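No paired analysis was possible because the lists give 1 set of calls per condition, with no values per replicate, and for the same reason no replicate could be left out. Motif settings and gene starts from transcripts were not run. The settings with gene bodies and with loops over 15 kb were chosen after the data were seen. Of 126 alternatives of the main values, 57 stayed within their 95% interval (the count of lists within 1.5 times) and 69 moved. Loops up to 1 Mb moved nothing because no loop was longer. A wider tolerance matches more calls by construction, and the other causes were not tested.

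Of loop sharing, 37.2% of the parental list, the value was 16.0% at a tolerance of 0 kb, 32.9% at 5 kb, 38.7% at 20 kb and 44.9% at 50 kb. It was 52.8% under the stricter threshold, 46.3% with equal list lengths, 39.1% for loops of 100 kb or longer and 39.4% for loops over 15 kb. For loop sharing, resistant list, in the same order, 35.4% became 15.2%, 31.4%, 36.8% and 42.8%, then 50.3%, 46.3%, 37.5% and 37.7%. Equal lengths kept the 5122 loops of lowest p-value per list. That setting removed weak calls from both lists, so its values do not show an effect of list length alone.

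For anchor sharing, 50.5% of parental anchors became 29.6% at 0 kb, 45.4% at 5 kb, 55.7% at 20 kb, 64.0% under the stricter threshold, 59.5% with equal lengths and 53.0% over 15 kb. For anchor sharing, resistant list, 48.2% became 28.2%, 43.5%, 53.4%, 61.8%, 59.7% and 50.7% in that order, and 49.4% on autosomes.

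Difference of medians in loop span, 0 kb, was -10.0 kb under the stricter threshold. The difference of shares planned for promoter loops, counted at either gene end, -0.866 points, was -3.42 points for loops of 100 kb or longer. It was -1.94 points (-3.82 to -0.203) with gene ends within 10 kb and -2.36 points (-3.76 to -0.675) with gene bodies, inside the main interval but excluding 0. Of the gene lists, 0 lay outside the limits with gene ends inside the anchor bin. In the loops per chromosome, X had a ratio of 1.67 under the stricter threshold. For the loops per chromosome, 7 had a ratio of 1.11 with equal lengths and, inside the main interval, 1.18 (0.970 to 1.43) under the stricter threshold.

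For boundary sharing, 82.4% of parental borders became 53.5% at 0 kb, 75.3% at 10 kb, 86.2% at 40 kb, 89.1% at 100 kb and 80.4% under the stricter threshold by score. For boundary sharing, resistant list, 78.5% became 50.9%, 71.8%, 82.1%, 84.9% and 75.7%. For domain sharing, 62.6% of parental domains became 28.7% at 0 kb, 53.7% at 10 kb, 68.0% at 40 kb, and 73.0% and 68.1% with reciprocal overlaps of 0.8 and 0.9. For domain sharing, resistant list, 59.6% became 27.3%, 51.2%, 64.8%, 69.5% and 64.9%. The difference in domain size, -10.0 kb, was -40.0 kb under the stricter threshold by score.

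For loops across boundaries, 3.73% of parental loops became 4.50% at 0 kb, 3.09% at 40 kb and 1.58% under the stricter threshold. For loops across boundaries, resistant list, 3.98% became 4.58%, 3.28% and 1.59%. For anchors at boundaries, 13.4% of parental anchors became 6.21% at 10 kb, 23.2% at 40 kb, 18.3% under the stricter threshold and 15.8% with equal lengths. For anchors at boundaries, resistant list, 14.7% became 6.83%, 24.2%, 20.3% and 18.0%.

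For 130 named genes under 12 settings, 1203 of 1560 differences equalled the main value, 346 moved and 11 took the opposite sign. Opposite signs were 1 for Cdkn1a and -1 for Hey1 and Plvap under the stricter threshold, -1 for Akr1b8 and Ptgs2 among loops of 100 kb or longer, -1 for Bcl2l1 and Ptgs2 with gene ends inside the bin, and -1 for Atm, Onecut2, Ptgs2 and 1 further gene with gene bodies. Of 160 list percentiles, 155 stayed on the same side of the limits.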

Other observations

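Gene families were also compared by symbol, after the data were seen, and some of them, such as the keratins, hold genes of the fixed lists. Loops at the 44 genes with symbols starting with Rps were mostly parental, with 10 parental-only loops and 1 resistant-only loop. The resistant-only share was 9.09% (0.230 to 41.3). Ribosomal proteins of the small subunit have such symbols, but the symbol alone does not show that all 44 genes encode them. Phosphodiesterase genes (Pde) had 2 and 9, a share of 81.8% (48.2 to 97.7), and Zbtb genes, zinc finger factors with a dimerising domain, had 4 and 11. Keratin genes (Krt) had 4 and 9. Rps was the only family of the 67 examined whose 95% interval excluded the 51.9% of all condition-specific loops, and with 67 intervals some are missed by chance.

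The tests of bins placed apart, of strength, of loop strength on chromosomes 7 and X and of the number of gene lists were chosen after the results they bear on were seen. Those of strength-matched loops on X and of shared loops at Hox genes were written down before, though the split of the X test by list was made afterwards.

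Most loops of each list had no match in the other, although under the stricter threshold loop sharing reached 52.8% of parental loops and loop sharing, resistant list, 50.3%. Displacement of the same loops by more than 10 kb does not account for most of them: 12.3% of parental-only loops (11.3 to 13.3) had a resistant loop within 50 kb at both anchors, where shifted lists gave 7.32%. Calls close to the caller's threshold could differ between lists without a difference between cells, and matching was 79.8 percentage points higher (76.9 to 82.7) in the strongest than in the weakest decile of parental loops. Gain and loss of loops with resistance remains open and was not tested, since each condition has 1 list. It also cannot be told apart from an effect of the gemcitabine treatment that only the resistant samples had.

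Chromosomes 7 and X had more resistant than parental loops, and few X loops had a match. If all contacts of chromosome 7 had been stronger to the same degree in resistant cells, as extra copies might give, -log10 p of loops found in both lists would have shifted by 0.829 to remove the excess. The shift against other chromosomes was 0.0574 (-0.284 to 0.359), and its difference from the needed one was -0.771 (-1.38 to -0.127). Loops found in both lists on chromosome 7 thus lacked a shift of that size. The needed shift takes strong and weak calls to move alike, and the model behind the p-value is unknown. These values therefore cannot exclude stronger contacts or extra copies. On X the shift was -0.120 (-0.646 to 0.5) over 25 loops, -0.672 (-1.33 to 0.201) from the needed 0.552, and uniformly stronger contacts cannot be told apart from other causes because so few loops were compared. Autosomal loops weighted to the p-values and spans of X had a match in 19.9% of parental loops, inside the X interval of 9.46 to 20.4, and in 19.7% of resistant loops, above the X interval of 6.94 to 15.2, so weak and short calls may account for the parental list but not wholly for the resistant list, and resistance itself was not tested.

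Hox genes had fewer resistant-only than parental-only loops. Counting of 1 loop at several neighbouring genes is a candidate explanation for the low percentile: with loops dealt out at random together with all their genes, 4.67% of draws gave a sum as low. The number of lists examined is another, since 29.4% of random dealings put at least 2 lists outside the limits, with a mean of 1.08 lists. A difference in Hox loops with resistance stays open and was not tested.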
